A study of Mus musculus with 8 samples.

How the data were processed

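Spleen cells of Foxp3 and Bach2 reporter mice were enriched for CD4 T cells and sorted by flow cytometry into Foxp3-GFP positive, Bach2-RFP HI or LO cells, and sequencing libraries were made with the SmartSeq2 method, per the labels' protocols. The series design text describes a different single-cell experiment and was not used for these samples. Each of the 8 libraries was placed in its group by its title. Labels name F1, F2, M1 and M2 in each group, but do not state that a HI and a LO library with the same label came from 1 animal, nor that the libraries came from separate animals, so the p-values measure the spread between these libraries.

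The deposited table holds FPKM values, fragment counts scaled by transcript length and library size, 1 column per library, which the authors made before deposit. FastQC, cutadapt and HISAT2, and the builds NCBIM37 and mm9, are named in the submitters' processing notes, without versions. Per the name of the deposited table, the authors took the FPKM values from Cuffnorm, which scales libraries to each other; the scaling method and the annotation are not given in the sources used here. FPKM values were used as deposited. Whether counting used strand is not given, so overlapping and antisense gene models cannot be told apart.

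Gene symbols were taken by Ensembl ID from a GENCODE annotation of another mouse build, and 31840 of the 36811 IDs matched, 10892 of the 11260 tested. That annotation was used for names, gene type, chromosome class, transcript length and GC content, and no coordinates are given. Length and GC content are those of a gene's longest annotated transcript. Of the 437 entries of the gene lists, 432 matched an ID in the table. Between 45.6% and 51.9% of a library's summed FPKM lay in models of short RNAs or models without a current symbol, and the top gene model alone took 24.5% to 30.4%, so FPKM sums are not depths. Relative depth was read from gene models below 2 FPKM in every library, as the most frequent ratio to HI F1. Between 56.4% and 86.0% of such ratios lay within 1% of a ratio of whole numbers up to 6 after division by the step, the lowest share in LO M2, the deepest library. Number of reads itself was not recovered.

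Genes with FPKM of at least 1 in at least 4 libraries were kept. Values were tested as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, with eBayes and a variance trend, and Benjamini-Hochberg adjustment at 0.05. A fold change on this scale understates the change of low genes, while folds in the text are ratios of mean FPKM. LO was compared with HI over all 8 libraries without covariates. Sex was compared on label means, 2 against 2, and the interaction of sex and reporter level over all 8 libraries. Gene lists were tested with camera at a preset correlation of 0.01, and for comparison with an estimated correlation and with fry. Bach2 and Foxp3 were also tested with a two-sided exact permutation test, which cannot go below 0.0286. Where a library is listed at 0, library values are given in place of a mean and no fold is given.

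The groups, tests, gene lists and alternatives were fixed before the data were examined. The lists cover resting and effector T cell states, Treg identity, transcription factors, trafficking, cell cycle, immediate early genes, metabolism, ribosomal and mitochondrial genes, cytokines, survival, interferon response and markers of other cell types. Genes were named by a rule fixed at the same time. It took Bach2 and Foxp3, the 8 genes with the largest rise and the 8 with the largest fall among genes with adjusted p below 0.05, no overlap between groups and a mean of at least 5 FPKM in the higher group, and up to 4 members of each list with the smallest p. It left out predicted gene symbols, receptor segments and small RNAs among the top genes. For sex it took Xist, 4 Y-linked genes and called autosomal genes, and for the interaction up to 5 called genes. List members outside the rule that are named were chosen after their values were seen. Of the genes the rule took, 2 are not reported here.

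The alternatives were a pseudocount of 0.1, no filter, a filter of FPKM at least 5, quantile normalization, upper quartile scaling, other eBayes settings, sex as a covariate, a 2-fold threshold, the label as a block and leaving out each library in turn. On simulated data with the means and spreads of the 11260 genes and 200 changed genes, the fit of LO against HI recovered 82.0% of genes changed by 3 on the log2 scale and 21.0% of those changed by 1, with 11 unchanged genes called. The simulated sex comparison recovered 12.0% and 0% of these and the simulated interaction 9% and 0%. For sex, the simulated label values had the spread of single libraries, while the real ones are means of a HI and a LO library. The simulation may thus understate what the sex comparison recovers.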

Results

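Gene expression was measured by RNA sequencing in regulatory T (Treg) cells from the spleens of C57BL/6 mice aged 12 to 13 weeks. The mice carried a Foxp3 reporter with green fluorescence, which marks Treg cells, and 1 Bach2 allele with a red fluorescent reporter (RFP). Foxp3-GFP positive cells were sorted into a Bach2-RFP HI and a Bach2-RFP LO population. Each population had 4 libraries, 2 labelled female (F1 and F2) and 2 labelled male (M1 and M2). The deposited values are FPKM for 36811 Ensembl gene models, of which 11260 passed the low-value filter and were tested. The FPKM of a library summed to between 1494240 and 2142813. Read totals are not in the table, but the steps between low values gave relative depths. Taking HI F1 as 1, HI F2 was at 1.27, HI M1 at 0.636, HI M2 at 0.818, LO F1 and LO F2 at 0.818, LO M1 at 1 and LO M2 at 5.27. LO M2 was thus the deepest library and had 14191 gene models above 0, against 11698 in HI M1, the shallowest. Spearman correlations over the tested genes were 0.893 to 0.931 within a group and 0.848 to 0.894 between groups. The first principal component held 31.5% of the variance and separated the HI from the LO libraries without overlap.

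The sort was made on the Bach2 reporter, so the level of Bach2 (ENSMUSG00000040270) itself checks the labels. Bach2 encodes a transcriptional repressor of the basic leucine zipper family. Its FPKM was 15.6 ± 5.56 in HI and 0.691 ± 0.187 in LO cells (SD, n = 4 each), and all 4 LO libraries lay below all 4 HI libraries. The log2 difference, LO minus HI, was -3.23 with a standard error of 0.34 (limma, adjusted p = 0.00057; exact permutation test, two-sided p = 0.0286, the smallest that 4 against 4 libraries can give). Foxp3 (ENSMUSG00000039521), the lineage transcription factor of Treg cells, stood at 14.2 ± 0.783 in HI and 14.7 ± 3.97 in LO cells. Its log2 difference of 0.01 had a standard error of 0.245 (limma, adjusted p = 0.985), so no difference in Foxp3 was detected beyond the spread between libraries. The 4 LO libraries ranged from 10.5 to 19.8, and the sign of this small difference turned when single libraries were left out.

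The comparison of LO with HI cells asks which genes differ between Treg cells with low and with high Bach2 reporter. Igfbp4, which encodes a binding protein of insulin-like growth factors, fell from 317 ± 105 to 2.11 ± 0.737 FPKM, 150-fold. Klrg1, an inhibitory lectin-like receptor of differentiated lymphocytes, rose from 0 in HI F1 and at most 9.27 in the other HI libraries to between 328 and 424 in the LO libraries. S100a4, a calcium-binding protein, rose from 34.5 ± 35.1 to 1935 ± 718 FPKM. In all, 934 genes had an adjusted p below 0.05 with limma, 524 higher and 410 lower in LO cells. Of the 934, 743 differed at least 2-fold, 438 upwards and 305 downwards. The 4 LO values lay beyond the 4 HI values in 911 of the 934 genes, and in 1699 (15.1%) of all tested genes, where chance gives 2.86%. Between the libraries numbered 1 (F1 and M1) and those numbered 2 (F2 and M2), compared after the data were seen, 1 gene passed, the immediate early gene Fos (limma adjusted p = 0.0438), and the fit of LO against HI on 2 against 2 libraries gave 20 genes for number 1 and 209 for number 2. With the library number as a covariate, chosen after the data were seen, 1032 genes passed. Without the shallowest and the deepest library, also chosen afterwards, 646 genes passed, and 561 of these were among the 934.

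Among the 8 genes that rose most in LO cells were 2 chemokine receptors. Ccr2 (ENSMUSG00000049103) rose from 2.17 ± 1.34 to 66.7 ± 21.0 FPKM, 30.7-fold (log2 difference 4.46, SE 0.402, limma adjusted p = 0.000295). Ccr10 was listed at 0 in 3 HI libraries and at 1.23 in HI M1, against 14.4 to 55.5 in the LO libraries. Gpr15, a homing receptor for the large intestine, was listed at 0 in 3 HI libraries and at 3.44 in HI F2, and at 26.8 to 56.2 in LO. Adam8, a membrane metalloprotease, was listed at 0 in 3 HI libraries and at 0.421 in HI F1, and at 14.7 to 55.2 in LO. Selenom, a selenoprotein of the endoplasmic reticulum, was listed at 0 in the 4 HI libraries and at 13.4 to 37.5 in LO. Ttc39c was listed at 0 in HI F1 and at no more than 4.29 in the others, against 55.0 to 92.3 in LO. Among the 8 genes that fell most were Dapl1, at 51.0 to 192 in HI and 0 to 9.63 in LO, and Cnn3, an actin-binding calponin, at 23.5 to 31.2 in HI and 0 to 1.01 in LO. Lad1 fell from 36.6 ± 2.83 to 2.58 ± 2.47 FPKM. Siglech, a lectin of plasmacytoid dendritic cells, was at 7.14 to 44.6 in HI and at 0, 0.760, 0 and 1.4 in LO. Klk1, a kallikrein, was at 11.1 to 35.4 in HI, at 0 in 3 LO libraries and at 2.68 in LO M2. Pdlim4 was at 8.56 to 45.1 in HI and at 0 to 1.92 in LO. The mitochondrial gene mt-Atp8 was listed at 29.0 to 111 in HI and at 0 in the 4 LO libraries, and divided by the relative value of 1 read the HI values stand as 3, 1, 1 and 1, which may be as many reads. Since mt-Co2, which every cell uses, is also listed at 0 in LO F2, a 0 here can be a failed estimate.

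**Figure D1:**
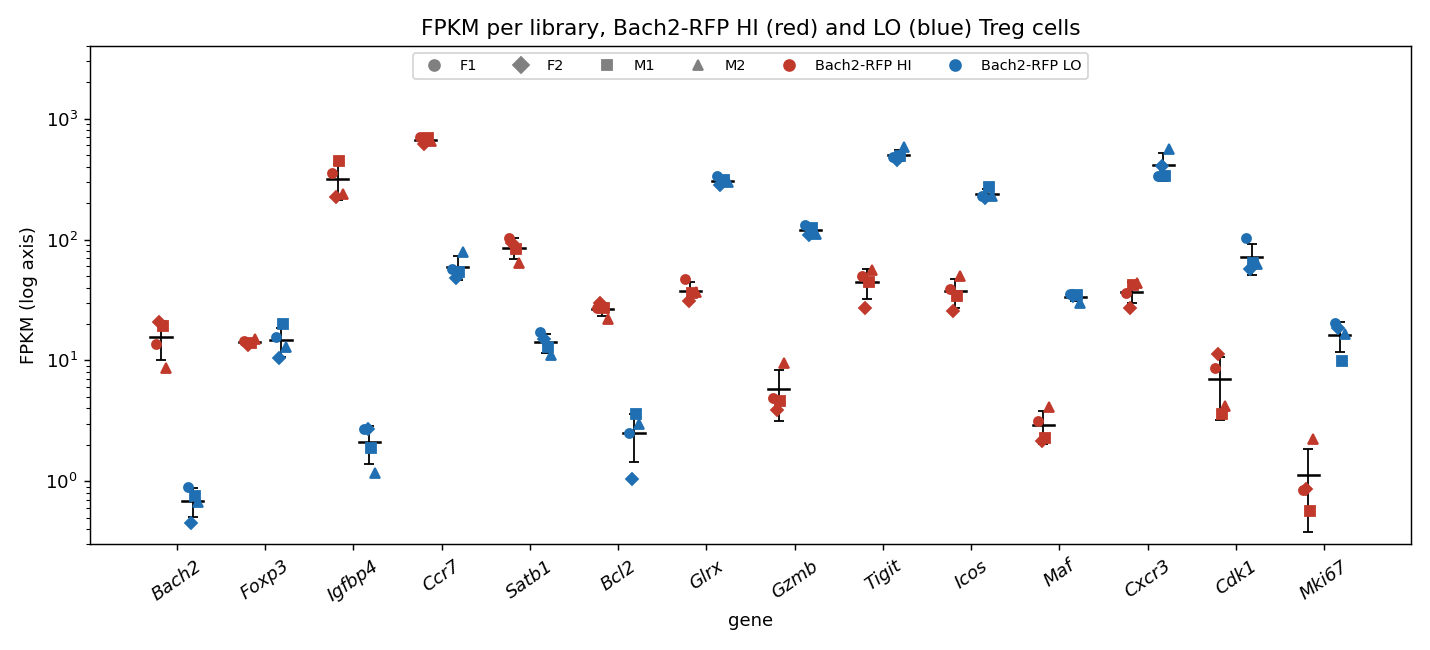
FPKM on a log axis for 14 genes in the 4 Bach2-RFP HI (red) and 4 Bach2-RFP LO (blue) libraries. Marker shapes give the label, and black bars the mean and SD (n = 4). Foxp3 overlaps between the groups, while Bach2 is at 8.62 to 20.7 in HI and 0.447 to 0.894 in LO.

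Genes of resting and naive T cells fell in LO cells. Of 24 measured genes of this list, 14 fell, 0 rose and 10 did not pass; adjusted over the list alone, 17 fell. Ccr7, the receptor that guides T cells to lymph nodes, fell from 669 ± 39.0 to 59.5 ± 13.6 FPKM, 11.2-fold (log2 difference -3.49, SE 0.166, limma adjusted p = 1.01e-05). Nsg2 fell from 65.7 ± 11.9 to 6.97 ± 2.11 FPKM, and Satb1, a chromatin organizer, from 85.8 ± 16.7 to 14.1 ± 2.58. Igfbp4 belongs to this list too. The list's median log2 difference was -1.35 (camera, adjusted p = 6.38e-18; adjusted p = 0.00207 with an estimated correlation). Bach2, on which the cells were sorted, is a member that fell; without it, a test chosen after the data were seen, 13 of 23 fell and the median was -1.3 (camera, adjusted p = 1.04e-16; adjusted p = 0.0017 with an estimated correlation). Some markers of B cells (5 of 17, with 1 lower) and of myeloid cells (5 of 11) were also higher in the HI libraries, and neither list was called with an estimated correlation.

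Genes of activated and effector Treg cells rose in LO cells. Of 33 measured genes, 26 rose and 1 fell; adjusted over the list alone, 28 rose and 1 fell. Glrx, a glutaredoxin, rose from 37.8 ± 6.62 to 307 ± 20.9 FPKM, 8.12-fold (log2 difference 3.0, SE 0.158, limma adjusted p = 1.8e-05). Gzmb, the cytotoxic protease granzyme B, rose from 5.74 ± 2.60 to 120 ± 11.3 FPKM, 20.9-fold. Tigit, an inhibitory receptor, rose from 44.2 ± 12.3 to 501 ± 53.9, and Icos, a costimulatory receptor, from 37.2 ± 10.2 to 238 ± 22.1. The member that fell was Il2ra, the alpha chain of the interleukin-2 receptor, with a log2 difference of -1.42. Over this list the median log2 difference was 2.1 (camera, adjusted p = 3.95e-28; adjusted p = 0.0016 with an estimated correlation).

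Transcription factors of effector Treg cells rose as a group, with 11 of 17 measured genes higher in LO cells and 0 lower; adjusted over the list alone, 12 rose. Rora went from 16.5 ± 3.93 to 110 ± 12.0 FPKM and Maf from 2.91 ± 0.893 to 33.7 ± 2.55. Batf, an AP-1 family factor, rose from 96.7 ± 11.2 to 277 ± 16.7, and Tbx21, which encodes T-bet, from 3.20 ± 1.54 to 21.0 ± 6.02. Across its members the median log2 difference was 1.51 (camera, adjusted p = 9.99e-12; adjusted p = 0.00207 with an estimated correlation). In the list of Treg identity genes 7 of 18 rose and 2 fell. Adjusted over the list alone, 7 rose and 4 fell. Itgae, Ctla4, Nrp1 and Tnfrsf18, which rose, and Il2ra, which fell, also belong to the list of activated and effector Treg genes. Itgae, the CD103 integrin chain, rose 8.40-fold to 123 ± 37.1 FPKM, Ctla4 rose from 101 ± 7.53 to 251 ± 32.4, and Capg rose 2.11-fold. Gpr83 fell from 120 ± 12.1 to 25.6 ± 12.7 FPKM, and Il2ra was the other member that fell. The Treg identity list had a median log2 difference of 0.281 (camera, adjusted p = 0.0325, or 0.295 with an estimated correlation). Its call was lost without HI M1 (adjusted p = 0.0532) and without LO M2 (adjusted p = 0.0757).

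Chemokine receptor and trafficking genes rose in LO cells, with 9 of 20 measured genes higher and 1 lower; adjusted over the list alone, 14 were higher and 1 lower. Cxcr3, a receptor that directs T cells to inflamed tissue, rose from 37.1 ± 7.54 to 411 ± 107 FPKM, 11.1-fold (log2 difference 3.43, SE 0.218, limma adjusted p = 5.31e-05). Itgb1, the integrin beta 1 chain, rose from 70.7 ± 5.17 to 398 ± 77.7. The member that fell was Ccr9, a gut homing receptor that plasmacytoid dendritic cells also carry, from 15.8 ± 4.69 to 3.02 ± 1.14. The list's median log2 difference was 1.53 (camera, adjusted p = 2.06e-12; adjusted p = 0.0079 with an estimated correlation).

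Cell cycle genes rose in LO cells, with 24 of 37 measured genes higher and 0 lower; adjusted over the list alone, 29 were higher. Cdk1, the mitotic kinase, rose from 6.95 ± 3.73 to 71.6 ± 20.7 FPKM, 10.3-fold (log2 difference 3.28, SE 0.356, limma adjusted p = 0.000619). Mki67, the proliferation marker Ki-67, rose from 1.12 ± 0.741 to 16.3 ± 4.65. Rrm2, a subunit of ribonucleotide reductase, rose 5.92-fold, and Plk1, a mitotic kinase, 6.54-fold. Over this list the median log2 difference was 1.54 (camera, adjusted p = 7.07e-20, or 0.0124 with an estimated correlation). Some markers of plasma cells (2 of 5) were also higher in the LO libraries, and their list was not called with an estimated correlation.

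Ribosomal protein genes fell in LO cells: 48 of 49 measured genes were lower and 0 higher, and 49 were lower adjusted over the list alone. Rpl13 fell from 3850 ± 484 to 1537 ± 55.1 FPKM, 2.50-fold (log2 difference -1.32, SE 0.123, limma adjusted p = 0.000329). Rps18 fell 2.74-fold, Rps20 3.14-fold and Rpl8 2.24-fold. These genes have many processed pseudogenes that can share reads with them, so their levels are uncertain. Across its members the median log2 difference was -1.18 (camera, adjusted p = 1.24e-44; adjusted p = 0.0528 with an estimated correlation). Of 13 measured mitochondrially encoded genes, 7 were lower and 0 higher in LO cells; adjusted over the list alone, 9 were lower. The transcript mt-Cytb fell from 4242 ± 269 to 2215 ± 315 FPKM, mt-Nd1 2.09-fold and mt-Co1 1.68-fold, the last with adjusted p = 0.209 under quantile normalization. The median of this list was -0.959 (camera, adjusted p = 3.9e-09; adjusted p = 0.0863 with an estimated correlation). HI M1 was the shallowest library and LO M2 the deepest, and both were set against the other libraries of their group. For transcripts of 1000 to 2000 bases the median log2 difference was 0.2 in HI M1 and 0.00612 in LO M2. For those of 500 to 1000 bases it was 0.297 and -0.353. The median length of the ribosomal protein genes (1151) lies in the longer class. That length is of each gene's longest annotated transcript, so the transcripts sequenced may be shorter.

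Glycolysis and oxidative phosphorylation genes were tested as separate lists. Of 16 measured glycolysis genes, 1 rose and 0 fell; adjusted over the list alone, 2 rose. Tpi1, triosephosphate isomerase, rose from 75.9 ± 8.68 to 134 ± 6.59 FPKM (log2 difference 0.82, limma adjusted p = 0.0059). Slc2a3, a glucose transporter, was at 48.6 ± 20.1 in HI and 91.3 ± 17.2 in LO (adjusted p = 0.0569), or adjusted p = 0.00913 without HI M2. Hk1 (adjusted p = 0.173) and Eno1 (adjusted p = 0.302) did not pass. The list's median was 0.235 (camera, adjusted p = 0.0237; adjusted p = 0.392 with an estimated correlation), and the call was lost without HI F1 (adjusted p = 0.0573), without HI F2 (adjusted p = 0.0526) and without LO M2 (adjusted p = 0.127). Of 25 oxidative phosphorylation genes, 0 rose and 0 fell, over all genes and adjusted over the list alone, with Ndufv1, Ndufa5, Sdha and Ndufb5 at adjusted p = 0.113, 0.123, 0.158 and 0.274. Without LO M2, Sdha had adjusted p = 0.0367. The list's median was -0.166 (camera, adjusted p = 0.0325, or 0.392 with an estimated correlation). Its call was lost without HI F2 (adjusted p = 0.0526), without HI M1 (adjusted p = 0.0609) and without LO M2 (adjusted p = 0.203). It was also lost under quantile normalization (median -0.0757, camera adjusted p = 0.312) and with the filter of FPKM at least 5 (camera adjusted p = 0.0548).

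Of 6 measured cytokine genes, 2 rose and 0 fell. Adjusted over the list alone, 4 rose. Ebi3, Il10 and Areg also belong to the list of activated and effector Treg genes, so for them this is no separate result. Ebi3, a subunit of interleukin-27 and interleukin-35, rose from 23.1 ± 9.05 to 94.1 ± 40.3 FPKM, with LO M2 at 154. Il10, an immunosuppressive cytokine, was listed at 0 in the 4 HI libraries and at 15.8, 1.32, 2.15 and 5.92 in LO (limma adjusted p = 0.0298). That call was lost when any 1 of the 4 HI libraries was left out (adjusted p = 0.0634 to 0.072) and without LO M2 (adjusted p = 0.0797). Areg was at 0 to 1.88 in HI and 2.39 to 30.7 in LO (adjusted p = 0.0669; adjusted p = 0.0465 without LO M1), and Tnf was at 6.83 ± 2.07 and 12.6 ± 3.22 (adjusted p = 0.171). The cytokine list's median was 1.58 (camera, adjusted p = 0.00958, or 0.197 with an estimated correlation). With the filter of FPKM at least 5 it was 0.984 and the call was lost (camera, adjusted p = 0.107).

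Of 14 measured survival and apoptosis genes, 2 rose and 1 fell, over all genes and adjusted over the list alone. Bcl2, which protects cells from apoptosis, fell from 26.5 ± 3.20 to 2.53 ± 1.08 FPKM, 10.5-fold (log2 difference -3.02, SE 0.309, limma adjusted p = 0.000527). It also belongs to the list of resting and naive T cell genes, so its fall is no separate result. Bid, a proapoptotic relative of Bcl2, rose 1.87-fold (adjusted p = 0.0393), a call that was lost without HI F1, HI F2, LO F1, LO F2 or LO M2 (adjusted p = 0.0818 to 0.098). Bcl2l11 was at 16.5 ± 2.92 and 8.32 ± 5.0 (adjusted p = 0.131; adjusted p = 0.0355 without LO F1). The list had a median of 0.108, a mean of -0.0073 and no call (camera, adjusted p = 0.908; adjusted p = 0.906 with an estimated correlation).

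Of 18 measured interferon response genes, 1 rose and 1 fell; adjusted over the list alone, 3 rose and 1 fell. Oas1a, an antiviral oligoadenylate synthetase, rose from 14.2 ± 4.83 to 51.0 ± 14.1 FPKM, and Usp18, a negative regulator of interferon signalling, fell from 67.4 ± 11 to 33.8 ± 4.50. Rsad2 did not pass (adjusted p = 0.0679; adjusted p = 0.0094 without LO F2), nor did Ifi27l2a (adjusted p = 0.084; adjusted p = 0.00684 without LO M2 and 0.00483 under quantile normalization). The list was not called (median 0.28; camera, adjusted p = 0.195; adjusted p = 0.575 with an estimated correlation).

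**Figure D2:**
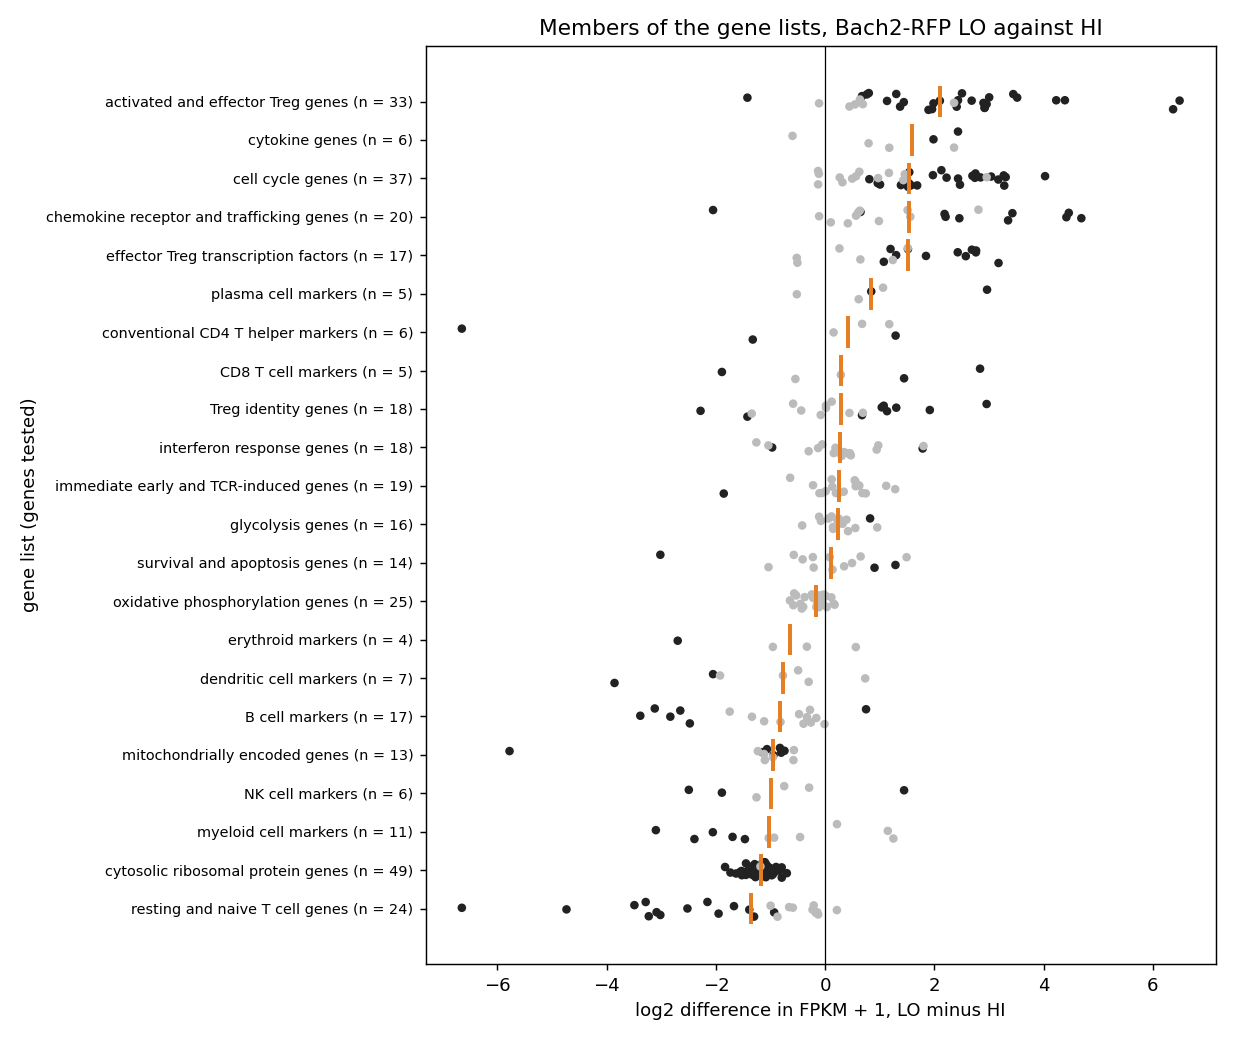
Log2 difference in FPKM + 1, LO minus HI, for each tested member of the 22 gene lists with at least 2 tested members. Dark points have a limma adjusted p below 0.05, grey points do not, and orange bars are list medians, from -1.35 for resting and naive T cell genes to 2.1 for activated and effector Treg genes.

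Of 19 measured immediate early and T cell receptor induced genes, 0 rose and 1 fell in LO cells, over all genes and adjusted over the list alone. Myc, a transcription factor of cell growth, fell from 110 ± 19.9 to 29.5 ± 4.09 FPKM (log2 difference -1.86, SE 0.187, limma adjusted p = 0.000485). Nfkbid (adjusted p = 0.151), Nfkbia (adjusted p = 0.187) and Tnfaip3 (adjusted p = 0.224) did not pass. The list was not called (median 0.244; camera, adjusted p = 0.345; adjusted p = 0.74 with an estimated correlation), and its median was -0.0626 without LO F1. Between the library numbers 1 member, Fos, passed and the others did not (adjusted p = 0.123 to 0.963). Fos, a subunit of AP-1 named after its values were seen, was at 1518 in HI F1 and 1454 in LO F1, and at 442 in HI M1 and 441 in LO M1. In the libraries numbered 2, Fos was at 46.0 in HI F2, 29.0 in LO F2, 23.6 in HI M2 and 20.8 in LO M2.

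**Figure D3:**
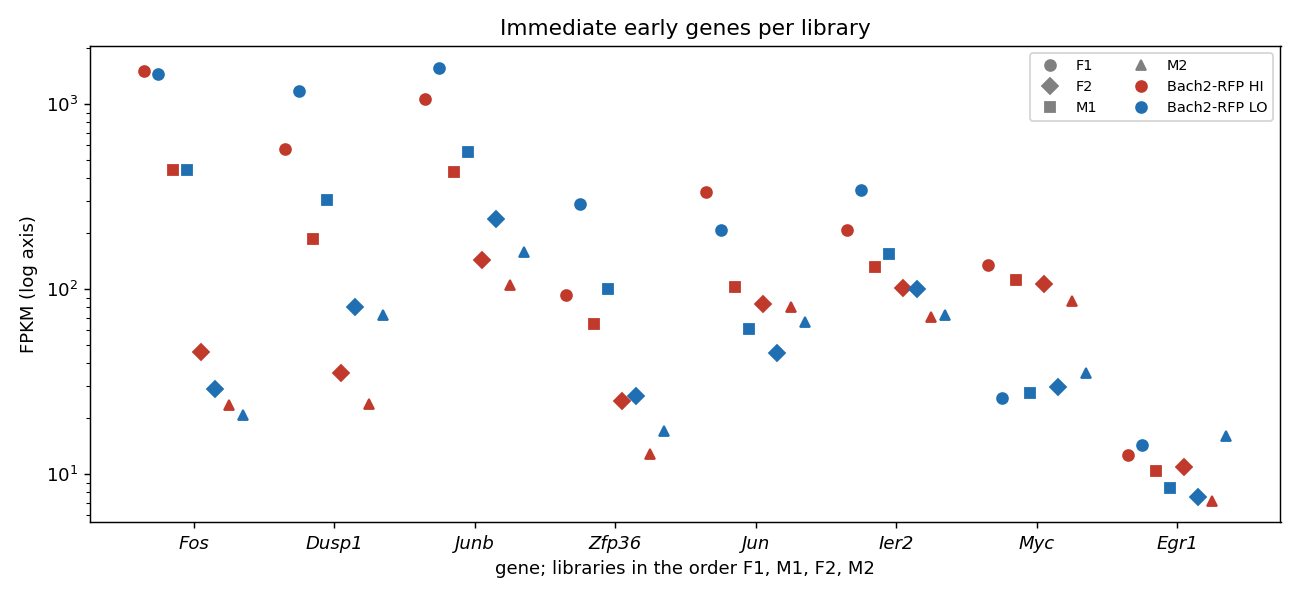
FPKM on a log axis for 8 immediate early genes in each library, drawn in the order F1, M1, F2, M2, with HI in red and LO in blue. Fos is at 441 to 1518 in the libraries numbered 1 and at 20.8 to 46.0 in those numbered 2.

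Markers of other cell types show what else the sorted populations could hold. Of 17 measured B cell markers, 5 were lower and 1 higher in LO cells, over all genes and adjusted over the list alone. Cd79a, a subunit of the B cell receptor, fell from 48.9 ± 16.6 to 4.61 ± 1.05 FPKM (log2 difference -3.12, SE 0.281, limma adjusted p = 0.000295). Ms4a1 was at 5.50 to 24.3 in HI and 0 to 1.95 in LO, and Spib at 3.99 to 18.0 and 0 to 1.4. The member that rose was Ighm, the immunoglobulin heavy constant mu gene (log2 difference 0.75, adjusted p = 0.0462). The B cell list had a median of -0.819 (camera, adjusted p = 0.000217; adjusted p = 0.0732 with an estimated correlation). Of 5 plasma cell markers, 2 rose and 0 fell, over all genes and adjusted over the list alone. Jchain, the joining chain of secreted immunoglobulins, rose from 10.8 ± 5.86 to 89.0 ± 50.4 FPKM, and Txndc5, a protein disulfide isomerase, rose 1.82-fold with a call that was lost in 6 of the 8 fits that left out 1 library (without HI F1, HI F2, HI M2, LO F2, LO M1 or LO M2, adjusted p = 0.0608 to 0.101). Iglv1 and Sdc1 did not pass (adjusted p = 0.422 for each). The plasma cell list had a median of 0.843 (camera, adjusted p = 0.0388, or 0.154 with an estimated correlation). Its call was lost without HI F2, HI M1, LO F2 or LO M1 (adjusted p = 0.0532 to 0.0667). It was also lost under quantile normalization (camera adjusted p = 0.0523) and with the filter of FPKM at least 5 (camera adjusted p = 0.0817).

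Of 11 measured myeloid markers, 5 were lower and 0 higher in LO cells; adjusted over the list alone, 6 were lower and 1 higher. C1qa, C1qb and C1qc, the chains of complement C1q made by macrophages, were among those that fell, C1qc from 23.5 ± 5.07 to 4.93 ± 1.5 FPKM. Csf1r, the macrophage colony-stimulating factor receptor, fell 3.21-fold. The myeloid list had a median of -1.03 (camera, adjusted p = 0.00155; adjusted p = 0.0863 with an estimated correlation). Of 7 dendritic cell markers 2 fell, Siglech and Ccr9, and 0 rose, over all genes and adjusted over the list alone (median -0.773; camera, adjusted p = 0.0114; adjusted p = 0.192 with an estimated correlation). Clec10a (adjusted p = 0.173) and Itgax (adjusted p = 0.412) did not pass, though without HI M1 Clec10a had adjusted p = 0.0131.

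Of 6 natural killer cell markers 1 rose and 2 fell, over all genes and adjusted over the list alone. Nkg7, a granule protein of cytotoxic cells, rose from 69.5 ± 22.1 to 191 ± 64.4 FPKM. Eomes was at 1.67 to 6.75 in HI and 0 to 0.426 in LO, with its call lost without HI M2 (adjusted p = 0.0506) and without LO F2 (adjusted p = 0.0543). Klrd1 was at 2.78 to 16.4 in HI and 0 to 4.32 in LO (adjusted p = 0.0424), with the call lost in 6 of the 8 fits that left out 1 library (without HI F1, HI M1, HI M2, LO F2, LO M1 or LO M2, adjusted p = 0.0877 to 0.112), and Gzma did not pass (adjusted p = 0.237). Of 5 CD8 T cell markers 2 rose, Ccl5 (7.06-fold) and Nkg7, and 1 fell, Eomes; adjusted over the list alone, 2 rose and 2 fell. Cd8b1 was at 41.0 ± 4.68 and 27.8 ± 4.12 (adjusted p = 0.119). Of 6 conventional CD4 T helper markers 1 rose, Tnfsf11 (2.51-fold), and 2 fell, Igfbp4 and Tnfsf8 (2.80-fold), over all genes and adjusted over the list alone, while Tnfsf14 did not pass (adjusted p = 0.339). The helper list had a median of 0.415 and a mean of -0.781, and camera pointed down without a call (adjusted p = 0.488), while fry called it downwards (adjusted p = 0.00229). Of 4 erythroid markers 1 fell, Car1, at 3.83 to 25.1 in HI and 0 to 4.47 in LO, over all genes and adjusted over the list alone. Its adjusted p of 0.0361 was lost without HI F1, HI M1, HI M2, LO F2, LO M1 or LO M2 (adjusted p = 0.0618 to 0.0965). The near-identical globin genes Hba-a1 (adjusted p = 0.762) and Hba-a2 (adjusted p = 0.683) and Alas2 (adjusted p = 0.795) did not pass, nor did Itgb3, the only measured platelet marker (adjusted p = 0.616). Camera called neither the natural killer (adjusted p = 0.118), the CD8 (adjusted p = 0.346) nor the erythroid list (adjusted p = 0.327). With an estimated correlation these and the helper list had adjusted p = 0.414, 0.583, 0.592 and 0.583.

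In all, camera called 15 of the 22 lists with at least 2 tested members, 8 upwards and 7 downwards in LO cells, and 5 held with an estimated correlation. These 5 were the resting, effector, transcription factor, chemokine receptor and cell cycle lists. Some of the 22 lists share members, so the 15 calls are not all separate results. Within the libraries numbered 1 camera called 9 lists, and within those numbered 2 it called 13.

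Female and male libraries were compared on the mean of the HI and the LO library of each label, 2 female labels against 2 male labels. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were listed at 0 in the 4 female libraries and were above 0 in the 4 male libraries. Eif2s3y, a translation initiation factor gene, was at 81.2, 48.6, 49.1 and 33.6 FPKM in HI M1, HI M2, LO M1 and LO M2 (limma adjusted p = 0.0335). Xist, the RNA that silences an X chromosome in females, was at 5.73 to 11.9 in female and at 0 in male libraries. With 2 labels per sex, 2 genes had an adjusted p below 0.05 and 377 an unadjusted p below 0.05, fewer than the 563 expected by chance. The other gene was the T cell receptor segment Traj56 (adjusted p = 0.00155), on values that may be 0 to 4 reads in each library, and Xist, Ddx3y, Kdm5d and Uty did not pass (adjusted p = 0.454, 0.391, 0.479 and 0.609). In a fit of all 8 libraries with reporter level as a covariate 5 genes passed, and Traj56 did not (adjusted p = 0.998). Among the 5 were Xist, Ddx3y and Kdm5d (limma adjusted p = 0.0251, 0.0112 and 0.041). That fit counts same-labelled libraries as separate samples. Without F1, F2, M1 or M2, Eif2s3y had adjusted p = 0.0516, 0.0555, 0.137 and 0.0921.

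The interaction of sex and reporter level asks whether the difference between LO and HI cells depends on sex. It was called for 2 of the 11260 genes, and 431 had an unadjusted p below 0.05, fewer than the 563 expected by chance. Traj56 was listed at 1978 in HI F1, 3108 in HI F2 and 0 in HI M1 and HI M2, and at 2418, 2418, 1978 and 1501 in LO F1, LO F2, LO M1 and LO M2 (limma adjusted p = 3.24e-05). Divided by the relative value of 1 read in each library, these stand as 1, 2, 0 and 0 in HI and 1, 1, 1 and 4 in LO, so the call sets 0 against what may be single reads. Mpc1-ps, a pseudogene of a mitochondrial pyruvate carrier gene, was at 0 in HI F1 and HI F2, 71.9 in HI M1 and 44.7 in HI M2, and at 22.4, 22.4, 18.3 and 10.4 in the same LO libraries (adjusted p = 0.0314). The call of Mpc1-ps was lost with each of the 8 libraries left out (adjusted p = 0.0829 to 0.3). Over all 11260 tested genes, the difference between LO and HI in females and that in males had a correlation of 0.485 and the same sign in 65.5%, taken across genes, which are not independent replicates.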

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

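Among the named genes, 198 groups of 4 libraries were checked for a library far from the other 3, and 21 stood apart. For normally distributed values chance gives about 1 in 20, or 9.9. FPKM values need not be normal, and a group with 0 in 3 libraries stands apart whatever its remaining value. This was so for Gpr15, Adam8 and Ccr10 in HI and for Klk1 and Clec10a in LO. The 21 thus cannot be read as an excess over 9.9. Of LO F1, Cdk1 was at 102 FPKM (56.7 to 64.5 in the other LO libraries), Nfkbia at 942 (492 to 499), Tnfaip3 at 145 (22.9 to 29.8), Areg at 30.7 (2.39 to 6.58), Hba-a1 at 130 (11.2 to 29.6) and Klrd1 at 4.32 (0 to 0.652). Of LO M2, the deepest library, Ccr2 was at 35.1 (76.3 to 78.3 in the others), Rps18 at 1521 (1955 to 2020), Ebi3 at 154 (67.7 to 78.3), Tpi1 at 144 (130 to 132), and Klk1 at 2.68 and Clec10a at 1.98, both listed at 0 in the others. Of HI M1, the shallowest library, Rpl8 was at 3330 (2834 to 2897), Rps18 at 6144 (4675 to 4799), Sdha at 829 (738 to 753) and Ccr10 at 1.23 (0 in the others). The other libraries that stood apart were HI F1 for Rora at 22.4 (14.3 to 14.8) and Adam8 at 0.421 (0), HI F2 for Gpr15 at 3.44 (0), HI M2 for Slc2a3 at 78.3 (35.3 to 42.6) and LO M1 for C1qc at 7.15 (3.84 to 4.37).

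The LO against HI effect differed between the sexes, by the interaction term, for Traj56 (-10.79, female minus male, on the log2 scale) and Mpc1-ps (6.51). Both were listed at 0 in the 2 HI libraries of 1 sex, Traj56 in males and Mpc1-ps in females, so the sizes depend on the pseudocount. Divided by the value of 1 read in each library, the Traj56 values above 0 stand at 1 to 4 times their lowest and those of Mpc1-ps at 1 to 3 times, so both effects may rest on a few reads.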

How the results depend on the processing

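The alternatives that used the library number, dropped the shallowest and the deepest library together, dropped a label from the sex comparison or dropped receptor segments and short RNA models from the interaction were chosen after the data were seen. The count of 934 genes stayed within 1.5 times under every alternative fixed before the data were examined, between 642 (without LO F2) and 975 (upper quartile scaling), with 949 under quantile normalization, 804 with a pseudocount of 0.1 and 752 with no filter. It fell to 209 with only the libraries numbered 2 and to 20 with only those numbered 1, which are fits with fewer samples. The labels do not say that same-labelled libraries came from 1 animal. Their deviations correlated at 0.052, 0.015, 0.07 and 0.11 for F1, F2, M1 and M2, which is low but above 0 for each label. The deviations of 6 of the 8 libraries correlated best, among the libraries of the other population, with those of their own label. Some immediate early genes, picked after their values were seen, fell in the order F1, M1, F2, M2 in both populations. Fos was at 1518, 442, 46.0 and 23.6 in HI and at 1454, 441, 29.0 and 20.8 in LO. Junb, Dusp1, Zfp36 and Ier2 kept this order too, while others, such as Jun and Egr2, did not. Same-labelled libraries from 1 animal would show this, but these are a few genes picked from many. A pairing by label is thus neither shown nor excluded. With the label as a replicate block 771 genes passed, 412 higher and 359 lower, and 698 of them were among the 934; Bach2 stayed at -3.23 and Foxp3 at 0.01, 15 lists were called, and 3 genes had an interaction. Calls that differed with the block were those of Bid (adjusted p = 0.0625), Txndc5 (0.0596), Tnfsf8 (0.0505), the Treg identity list (0.067) and the Mpc1-ps interaction (0.07), which did not pass with it, and of Tnfaip3 (0.0496), Areg (0.0497), Ifi27l2a (0.0185) and the immediate early list (0.0487), which did.

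Bach2 was called under each alternative (log2 difference -4.26 to -3.08) except within number 1 (-3.25, adjusted p = 0.0722) and number 2 (-3.21, adjusted p = 0.0597), fits with fewer samples. Foxp3 was called under none of its alternatives (adjusted p = 0.737 to 0.991); leaving out 1 library gave -0.13 to 0.15, with a turned sign without HI F2 (-0.02), LO F1 (-0.02) and LO M1 (-0.13), and number 2 alone gave -0.26. The cause was not tested. Camera called 15 lists, 12 to 15 with 1 library left out, 5 with an estimated correlation and 9 within number 1. Fry called 14, with the helper list (adjusted p = 0.00229) and without the glycolysis (0.0637) and oxidative phosphorylation (0.13) lists. The sex comparison gave 2 genes, 1 with a pseudocount of 0.1, 1 with no filter, 5 with all 8 libraries, and 2 to 6 with a label left out, where the lone label of a sex is assumed to vary like the others. The interaction gave 2 genes, 1 with no filter, 1 without receptor segments and short RNA models, and 1 to 2 with 1 library left out. The cause was not tested.

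Directions that turned, in results not called before or after, were the helper list under no filter (median 0.486, against 0.415, camera pointing up), the survival list, whose test turned from up to down under fry (median 0.108), without HI M1 (0.105), LO F1 (0.0425) or LO M1 (0.145) and within number 2 (-0.02), and the immediate early list without LO F1 (-0.0626). With 1 library left out these lists ranged from 0.0425 to 0.175 (survival) and from -0.0626 to 0.564 (immediate early). Over all alternatives, the named genes gave 1667 results with direction and call kept, 146 with the call lost and 15 with a call gained; for the lists these were 387, 44 and 2. Single genes that turned were Alas2 without HI M1 (0.079) or LO F2 (0.0076), within -0.61 to 0.079 with 1 library left out, Hba-a1 without LO F1 (-0.081), within -0.081 to 1.12, and Hba-a2 without LO F2 (0.23), within -1.88 to 0.23. The median log2 difference of all genes was -0.026, 0.002 after upper quartile scaling and -0.029 after quantile normalization. Relative depth limits what LO and HI libraries show of low genes, since 1 read is worth 1.57 times as much FPKM in HI M1, and 0.19 times as much in LO M2, as in HI F1.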

Other observations

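Gene groups in this and the next paragraph were chosen after the data were seen. S100 genes, which encode small calcium-binding proteins, rose in LO cells: 5 of 9 measured genes were higher and 0 lower, over all genes and adjusted over the list alone. Of the 5, 4 also belong to the list of activated and effector Treg genes, so this is no separate result. S100a6 rose from 65.5 ± 21.8 to 1464 ± 648 FPKM, S100a10 from 1035 ± 50 to 4105 ± 931 and S100a11 from 184 ± 51.8 to 1050 ± 308 (SD, n = 4 each; limma adjusted p = 0.000262, 0.000277 and 0.000608). The median log2 difference was 1.96 (camera, adjusted p = 4.01e-07; adjusted p = 0.133 with an estimated correlation). Of 17 replication-dependent histone genes, 2 rose, Hist1h1b and Hist1h2ab, and 0 fell (adjusted over the list alone, 3 rose and 1 fell; camera, adjusted p = 0.133). Of 8 tubulin genes, 2 fell, Tubb2a from 20.8 ± 3.77 to 2.01 ± 1.22 and Tuba4a from 193 ± 19.7 to 112 ± 13.9 FPKM (adjusted over the list alone, 2 rose and 2 fell; camera, adjusted p = 0.526).

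Genes for translation factors and ribosome-associated proteins fell in LO cells, with 9 of 20 lower and 0 higher; adjusted over the list alone, 17 were lower. Npm1, a nucleolar protein, fell from 935 ± 153 to 418 ± 35.1 FPKM and Rack1 from 4134 ± 357 to 2300 ± 134. The median log2 difference was -0.666 (camera, adjusted p = 3.39e-12; adjusted p = 0.0845 with an estimated correlation). Mitochondrial ribosomal protein genes had a median of -0.185 with 1 of 77 lower, Mrpl30, and 0 higher (adjusted over the list alone, 0; camera, adjusted p = 0.00772; adjusted p = 0.565 with an estimated correlation). Neither the 8 GIMAP genes nor the 36 proteasome genes had a called member (camera, adjusted p = 0.526 for each list).

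In the tests that follow, those of B cells, of myeloid cells, of chance variation in immediate early genes, of lists and of 0 values between library numbers and of splits by kind were chosen after the result was seen. Other splits of the 8 libraries 4 against 4 test whether the grouping matters. Of 35 splits, 1, the real one, gave as many as 934 genes, and the highest other split gave 6. A share of 1 of 35 is the smallest that this test can give. Every other split mixes HI and LO libraries, which widens the spread within its groups and lowers its count. The test thus makes chance unlikely for this count but does not exclude it. For the lists called by camera at the preset correlation, 2 of the 35 splits gave as many as 15, the real one included, and the highest other gave 15, so chance cannot be excluded for the number of lists. That other split set HI F1, HI M1, HI M2 and LO M1 against the rest, so it carries part of the difference between HI and LO, and it called 0 genes. The 18 splits with 2 libraries of each population in each group gave 0 to 3 lists, and the 16 with 3 libraries of one population and 1 of the other gave 6 to 15.

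Ribosomal protein genes were lower in LO cells, with a median log2 difference of -1.18 (quartiles -1.34 and -1.04). The 166 genes nearest to them on transcript length, GC content and expression level had a median of -0.0629 (quartiles -0.37 and 0.127). Their median GC content was 51.2% against 51.8%, which argues against GC content as the cause. Their median length was 1479.5 bases against 1151 and their mean log2 level 9.64 against 10.6. With this incomplete match, length and level cannot be decided. The tables argue against the shallowest and the deepest library, since the median was -0.99 without HI M1 and LO M2. Reads shared with pseudogenes cannot be told apart from a change of the genes: 29 ribosomal protein pseudogene models had a median of -1.02, and a fall of such models, set beforehand as evidence against shared reads, is also what models that collect reads of the genes would show. A difference between cells of high and low Bach2 reporter stays open, untested, with the list's call at adjusted p = 0.0528 under an estimated correlation.

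In HI cells 5 of 17 B cell markers and 5 of 11 myeloid markers were higher and 1 B cell marker lower, with list calls that were lost with an estimated correlation (adjusted p = 0.0732 and 0.0863), and some cells of these types may have passed the sort. Neither source is excluded: across the 4 HI libraries the 17 B cell markers had a mean pairwise correlation at percentile 93.6 of 2000 random lists matched on level, and the 11 myeloid markers at percentile 63.3, and 4 libraries are too few to tell. Of 7 dendritic cell markers, 2, Siglech and Ccr9, were higher in HI cells as well (list by camera, adjusted p = 0.0114, or 0.192 with an estimated correlation). Dendritic cells among the sorted HI cells were not tested. Of the abundant B cell genes, Cd74 was at 736 to 988 in HI and 624 to 1207 FPKM in LO and Ighm was higher in LO, but their level in LO cells would hide a small share, and 6 of the 17 B cell and 4 of the 11 myeloid markers averaged at least 10 FPKM in LO cells, with 0 held by another list. The CD4 enrichment and the sort on Foxp3-GFP were meant to remove B cells and myeloid cells. Foxp3 was at 14.2 in HI and 14.7 in LO, but with a standard error of 0.245 on the log2 scale this could not show a small share of other cells. Expression of these genes by Treg cells with high Bach2 reporter stays open and was not tested.

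Of 19 immediate early genes, 11 were higher in number 1 in all 4 pairs of libraries, with a median log2 difference of 0.812 over genes and pairs, and the list was called between numbers (camera, adjusted p = 2.51e-08; adjusted p = 0.35 with an estimated correlation). The tables argue against a shift of all genes at the same level, since matched genes had a median of 0.0585. Chance variation of single libraries cannot be told apart: the difference between numbers correlated across these genes between HI and LO cells at 0.808 in females and 0.828 in males, but genes that rise and fall together in a library would show this too, and neither the estimated correlation nor fry (adjusted p = 0.113) called the list. A batch acting on many genes cannot be told apart from an animal or handling effect: 1 gene, Fos, passed (limma adjusted p = 0.0438), but in that fit of 8 libraries with reporter level as a covariate 1145 genes had an unadjusted p below 0.05, against 563 expected, 441 for sex and 473 for the remaining pairing of labels in the same kind of fit, and camera called 8 of 22 lists, ribosomal protein genes included (0 with an estimated correlation), and 9 gene models were at 0 in all 4 libraries of number 1 and above 0 in all 4 of number 2, 0 the other way, against 0 and 3 for the remaining pairing, so the absence of further calls, set beforehand as evidence against a batch, was too strict. Number 1 holds the shallowest and number 2 the deepest library, which may also move these values (HI M1 was high and LO M2 low in Rps18), the labels give no batch, day or animal, and differences between animals stay open, untested.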
